A study of Rhodopseudomonas palustris with 8 samples.

How the data were processed

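The series holds 8 arrays: wild type and a hopanoid synthesis mutant of R. palustris TIE-1, each with succinate or pyruvate, 2 arrays per group. Per the labels' protocols, mid-log cells were washed and frozen, 3 biological replicates of an experiment were pooled, RNA was extracted with DNase treatment, and 500 ng was reverse transcribed with an oligo-dT primer carrying a T7 promoter, transcribed to cRNA and labelled with Cy3. Oligo-dT primes on poly(A) tails, which are short or missing on most bacterial transcripts, so how evenly transcripts were copied is not known. The files hold Agilent scanner output; per the file headers, it was made with Agilent Feature Extraction 11.5.1.1, the tool the labels name, and the processed intensity of each spot is background-corrected and not scaled between arrays. The authors also deposited a table of log2 values per gene. Set against the scanner values, each of its columns was the mean log2 processed intensity per gene minus the array's median (r 0.998 to 1.000, slope 0.986 to 1.000, column medians 0.0082 to 0.016), so its scale, centring and direction follow from that comparison; it served as an alternative.

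Groups were taken from the labels. Values were log2 of the processed intensity minus each array's 75th percentile over non-control spots; outlier spots were left out, spots of a probe were averaged, and the probes of a gene were averaged (4389 genes had 3 probes, 732 had 2 and 106 had 1). A probe was kept if well above background on both arrays of at least 1 group, which removed 0 probes. The 4 simple contrasts of the group means and their interaction were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 8 arrays, with 4 residual and 2.96 prior degrees of freedom and Benjamini-Hochberg adjustment over 5227 genes. A gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale with their standard errors.

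There were 29 gene lists, fixed by product text before the data were examined; product texts matched by accident were taken out afterwards, from the text alone. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera compares a list's genes with the other genes, so a called list is higher or lower relative to these. An estimated correlation and fry were alternatives. With the estimated correlation 0 lists passed in any contrast, also 1 whose estimate was -0.03. Failing there thus does not by itself show that correlation between genes undid a call. For the other lists called, the estimates ran from 0.12 to 0.85, above the preset 0.01, so their camera p-values at the preset may be too small. The genes named were set by a rule fixed beforehand. For each of the 4 simple contrasts they were the 6 largest rises and 6 largest falls among called genes with a named product whose arrays did not overlap between groups, the called member of each list with the largest rise and the largest fall, and every hopanoid gene. For the interaction they were the 5 largest in each direction. Of these, the text gives a part. The genes of the run of phage-type genes and those opening the other observations were chosen after their values were seen.

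Names are the product texts of the array's design. Of its locus tags, 0 matched the reference table given for this work, which is of another strain with 5034 genes, so no symbols or coordinates are given; the genome build is not given in the sources used here. Probes for near-identical genes may cross-hybridise, so values of paralogs such as the TonB receptors, chemotaxis proteins and nitrogenase isozymes are uncertain. All arrays lay on 1 slide. Each carbon source had its own slide row and each strain its own columns, so position and group cannot be told apart.

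The procedure was tested on simulated data for the comparison of mutant and wild type in succinate over 5227 genes. It recovered 11 of 100 genes changed by 1 on the log2 scale and 71 of 100 changed by 2. There were 3 false calls among 85, and 0 calls in an unchanged comparison. The simulated noise was independent between genes and arrays, with variances drawn from the fitted prior. It held no differences in array range and none shared between groups, both seen on the real arrays. The simulation therefore does not give the rate of false calls in the real data. Alternatives were normexp background (offset 50), quantile normalization, median scaling, no filter, only probes well above background on all 8 arrays, the brightest probe or median of probes per gene, the replicate number as a block, only the groups compared, a trended robust variance, a change of at least 1 on the log2 scale, the deposited table and each array left out. Leaving out the run of phage-type genes and the lists before correction were added after the data were seen. The normexp offset is added to every signal, so it shrinks large falls of dim genes by construction. A call of such a gene that ended there does not by itself show that the fall was absent.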

Results

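Transcript levels were measured in Rhodopseudomonas palustris TIE-1, a purple non-sulfur bacterium, in the wild type and in a mutant in hopanoid synthesis. Hopanoids are membrane lipids built from squalene, and squalene-hopene cyclase makes the first hopanoid of the pathway. The labels do not name the mutated gene. Each strain was grown with 10 mM succinate or 10 mM pyruvate as carbon source and harvested in mid-log phase. The 8 one-colour arrays formed 4 groups of 2. Each array held 15208 non-control spots, 14737 probes and 5227 genes, of which 3704 had a named product. Median spot signals ran from 158 to 507, between 97.2% and 100% of spots were well above background, and 0 were saturated. The correlation between the 2 arrays of a group, across genes, was 0.979 in wild-type succinate, 0.987 in mutant succinate, 0.979 in wild-type pyruvate and 0.953 in mutant pyruvate. The number of arrays limits the precision of every value. The labels describe pooled cultures and do not say which cultures lie behind each array, so p-values measure only the spread between these arrays, which may be partly technical.

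The first comparison asked which transcripts differed between the mutant and the wild type in succinate. Squalene-hopene cyclase (Rpal_4261) fell by 4.90 ± 0.36 on the log2 scale (SE, 2 arrays per group), which is 29.8-fold, with an adjusted p of 0.0038. Its call ended with normexp background (-2.78, adjusted p = 0.0819), and over the other alternatives that gave it a value its adjusted p ran up to 0.0447. The labels do not name the mutated gene, and DNA was not measured. Reduced expression of the cyclase and loss of its sequence can therefore not be told apart in either medium. The neighbouring hopanoid-associated phosphorylase (Rpal_4260) fell by 2.59 ± 0.31, a call that also ended with normexp background. Of the 7 hopanoid genes measured, Rpal_4261 and Rpal_4260 passed the test and 5 did not, and the same counts held when adjusted over the list alone. The others were squalene synthase HpnC (Rpal_4264) at 0.03 ± 0.28, HpnD (Rpal_4263) at -0.82 ± 0.41, the radical SAM protein HpnH (Rpal_4256) at -0.12 ± 0.22, the RND-type transporter (Rpal_4254) at -0.11 ± 0.27 and the FAD-dependent desaturase (Rpal_4262) at 0.05 ± 0.23. In all, 79 genes were higher and 224 lower in the mutant.

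Genes for flagella and chemotaxis were lower as a group in succinate: 13 of 68 fell and 1 rose, or 29 and 1 when adjusted over the list alone, and the list shifted down with a camera adjusted p of 4.9e-05. Like the other 6 list shifts called in succinate, it did not pass with an estimated correlation (adjusted p = 0.969 for each of the 7). By fry, nitrogen regulation (adjusted p = 0.033) and the Calvin cycle (0.029) passed. Flagella and chemotaxis (0.11), hydrogenases (0.13), aromatic degradation (0.14), chaperones (0.37) and light harvesting (0.58) did not. The flagellar hook capping protein (Rpal_1494) fell by 2.96 ± 0.46, and a methyl-accepting chemotaxis protein (Rpal_2025) rose by 1.39 ± 0.30. In ammonium assimilation and nitrogen regulation 4 of 11 fell, 7 when adjusted over the list alone, with a camera adjusted p of 0.0059 (0.969 with an estimated correlation). The nitrogen regulatory protein P-II (Rpal_0277), a signal protein of nitrogen status, fell by 3.42 ± 0.28. In the Calvin cycle list 3 of 6 fell, 4 when adjusted over the list alone, also at 0.0059 (0.969 with an estimated correlation), and ribulose-bisphosphate carboxylase (Rpal_1747), the carbon-fixing enzyme, fell by 1.86 ± 0.22. The hydrogenase list lay lower at 0.020 (0.969 with an estimated correlation), with 0 of 10 members past the limma threshold over all genes, 6 lower at an unadjusted p under 0.05 and 3 lower when adjusted over the list alone. The hydrogenase cytochrome b subunit (Rpal_1156), which is not in that list, fell by 2.28 ± 0.35. The aromatic degradation list lay lower at 0.037 (0.969 with an estimated correlation), with 3 of 23 lower and 1 higher, both over all genes and adjusted over the list alone. Benzoyl-CoA reductase subunit D (Rpal_0727) fell by 1.27 ± 0.22, and the 4-hydroxybenzoyl-CoA reductase beta subunit (Rpal_0739) rose by 1.84 ± 0.24. Chaperones and heat shock genes lay higher at 0.013 and light-harvesting and reaction centre genes at 0.037 (each 0.969 with an estimated correlation). Of their members, 0 of 22 and 0 of 15 passed in limma on either count, with 4 higher and 1 lower against 0 and 0 at an unadjusted p under 0.05. Quantile normalization ended the calls of the hydrogenase, chaperone and light-harvesting lists, and normexp background those of hydrogenase and aromatic degradation. With the replicate number as a block the hydrogenase list was at a camera adjusted p of 0.0512. The light-harvesting list was at 0.14 without wild-type succinate array 1 and 0.27 without mutant succinate array 2. Aromatic degradation was at 0.12 without wild-type succinate array 2, 0.17 without mutant succinate array 1 and 0.14 with the list before product texts were taken out.

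Other large changes in succinate fell outside these lists. The beta-Ig-H3/fasciclin protein (Rpal_0221) rose by 2.94 ± 0.54, intracellular septation protein A (Rpal_0206) by 2.06 ± 0.21, 4-hydroxyphenylpyruvate dioxygenase (Rpal_0005) by 1.75 ± 0.27 and an ATPase domain protein (Rpal_1544) by 1.72 ± 0.29. A putative rhizosphere induced protein (Rpal_1847) fell 16.0-fold, and its neighbour D-tyrosyl-tRNA deacylase (Rpal_1846) fell by 3.96 ± 0.37. An ECF-type sigma factor (Rpal_5278) fell by 2.51 ± 0.31, a thiol-disulfide isomerase (Rpal_4075) by 2.25 ± 0.25, a porin (Rpal_0539) by 1.87 ± 0.19 and an HAE1-family efflux transporter (Rpal_3305) by 1.81 ± 0.29. The 303 calls were 27 with normexp background (6 of the 32 named calls, without Rpal_0277), 620 with quantile normalization, 545 with a trended robust variance, 38 or 25 without wild-type succinate array 1 or 2, 7 or 8 without mutant succinate array 1 or 2 and 147 without either wild-type pyruvate array. Of the 32 named calls 2, Rpal_4261 and Rpal_0277, passed in all 8 leave-outs. The split also moved with the scaling, to 255 higher and 365 lower after quantile normalization and 147 and 200 after median scaling, against a median change over all genes of -0.23 in the main scaling, 0.03 after quantile normalization and -0.07 after median scaling.

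The second comparison asked the same of pyruvate cultures. Squalene-hopene cyclase (Rpal_4261) was at least 23.2-fold lower in the mutant (adjusted p = 0.0011). It had a probe well above background on 1 of the 2 mutant arrays, so this is a bound and the fitted value of -5.71 ± 0.36 is not a measured size. Its call ended with normexp background (-2.23, adjusted p = 0.12), and over the other alternatives that gave it a value its adjusted p ran up to 0.0204. The phosphorylase (Rpal_4260) fell by 2.34 ± 0.31, also not called with normexp background. As in succinate, the other 5 hopanoid genes did not pass, with 2 of 7 lower also when adjusted over the list alone; their values ran from -0.63 ± 0.41 for HpnD (Rpal_4263) to 0.51 ± 0.23 for the desaturase (Rpal_4262). The level of 2-ketocyclohexanecarboxyl-CoA hydrolase (Rpal_0720), an enzyme of aromatic ring degradation, fell by 6.09 ± 0.76, and the ammonium transporter (Rpal_0278) fell by 3.05 ± 0.31. In all, 193 genes were higher and 454 lower in the mutant.

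**Figure D1:**
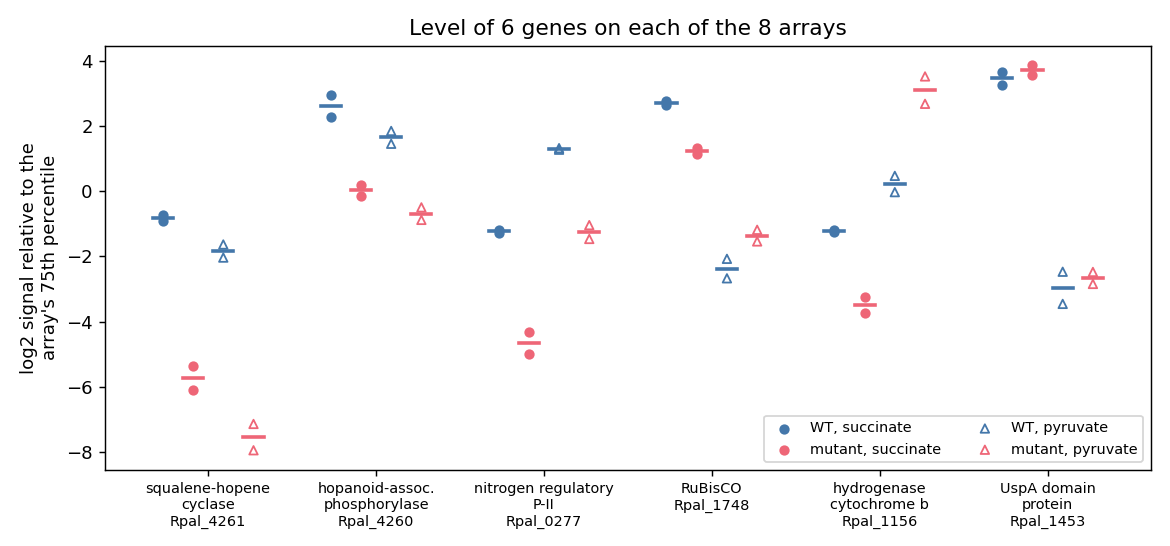
Level of 6 genes on each of the 8 arrays, as log2 signal relative to the array's 75th percentile; each symbol is 1 array, short lines are means of the 2 arrays of a group, colour gives the strain and symbol the carbon source. Mutant minus wild type was -4.90 (succinate) and -5.71 (pyruvate) for squalene-hopene cyclase, the latter not a measured size since 1 of its 2 mutant arrays was not well above background, and -2.28 and 2.88 for the hydrogenase cytochrome b subunit (Rpal_1156).

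In pyruvate the hydrogenase list lay higher in the mutant (camera adjusted p = 0.00014), with 2 of 10 members higher and 4 when adjusted over the list alone. Like the other 5 list shifts called in pyruvate, it did not pass with an estimated correlation (adjusted p = 0.883 for each of the 6). None of the 6 passed by fry either (adjusted p from 0.0945 for flagella and chemotaxis to 0.506 for NADH:quinone oxidoreductase). The 2 members were a hydrogenase formation protein (Rpal_1157) at 2.45 ± 0.42 and the large subunit (Rpal_1155) at 1.714 ± 0.321. The hydrogenase cytochrome b subunit (Rpal_1156), which by its product text is in the cytochrome list and not in this one, rose by 2.88 ± 0.35. Transposases and phage genes lay lower (0.00014, and 0.883 with an estimated correlation), with 9 of 65 lower and 12 when adjusted over the list alone. This list can share genes with the run of phage-type genes described below, so the 2 are not separate results. Its camera call held with that run left out. Flagella and chemotaxis lay lower (0.0019, and 0.883 with an estimated correlation), with 8 of 68 lower on both counts, among them the motor switch protein FliG (Rpal_1458) at -1.86 ± 0.22. Chaperones lay higher (0.00020, and 0.883 with an estimated correlation) with 0 of 22 past the limma threshold on either count and 3 higher and 1 lower at an unadjusted p under 0.05. Ribosomal proteins lay higher only relative to the other genes (0.0015, and 0.883 with an estimated correlation). Their median change was 0.03, with 27 of 52 members positive, against a median of -0.38 over all genes. On both counts 5 of 52 were higher and 1 lower. Ribosomal protein S19 (Rpal_3663) rose by 0.99 ± 0.21 and S6 (Rpal_3487) fell by 0.94 ± 0.23. NADH:quinone oxidoreductase genes lay higher (0.0015, and 0.883 with an estimated correlation), although the 1 member of 34 past the threshold, the D subunit (Rpal_3297), fell by 1.06 ± 0.23, and 0 passed in limma when adjusted over the list alone (3 higher and 1 lower at an unadjusted p under 0.05). Quantile normalization ended the call of ribosomal proteins, which were at 0.15 without wild-type pyruvate array 2 and 0.20 without mutant pyruvate array 1; the NADH:quinone oxidoreductase list was at 0.32 without mutant pyruvate array 1.

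Further rises in pyruvate were 4-hydroxyphenylpyruvate dioxygenase (Rpal_0005) at 2.58 ± 0.27, isocitrate lyase (Rpal_4878), the entry enzyme of the glyoxylate cycle, at 2.33 ± 0.31, an iron-containing alcohol dehydrogenase (Rpal_1398) at 2.27 ± 0.33 and a CsbD family protein (Rpal_4698) at 2.25 ± 0.53. The last was at 1.37 without mutant pyruvate array 2, and its call passed in 2 of 8 leave-outs. Cytochrome c oxidase subunit III (Rpal_1639) fell by 3.25 ± 0.45, the nitrogen fixation protein NifX (Rpal_5096) by 1.89 ± 0.38, a TonB-dependent receptor (Rpal_2651) by 1.86 ± 0.33, ATP synthase subunit A (Rpal_0914) by 1.76 ± 0.26, bacteriochlorophyll 4-vinyl reductase (Rpal_1863) by 1.75 ± 0.26 and trehalose-phosphate synthase (Rpal_3836) by 1.51 ± 0.22. With normexp background Rpal_2651 was at -0.54 (limma adjusted p = 0.788). The 647 calls were 13 with normexp background (2 of the 41 named calls, Rpal_0005 and Rpal_0278), 1018 with quantile normalization, 16 when the spread came from the pyruvate arrays alone, 29 or 24 without wild-type pyruvate array 1 or 2, 337 without mutant pyruvate array 1, 198 without either mutant succinate array and 426 without either wild-type succinate array. Of the 41 named calls 2, Rpal_4261 and Rpal_3048, passed in all 8 leave-outs. The split was 508 higher and 510 lower after quantile normalization and 383 and 308 after median scaling, with a median change over all genes of -0.38 in the main scaling, -0.03 after quantile normalization and -0.12 after median scaling.

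A run of 60 neighbouring locus tags, Rpal_3023 to Rpal_3082, was low on the mutant arrays in both carbon sources; it was found by a scan made after the values were seen. The run holds phage-type genes and many hypothetical proteins. Its median fitted change was -2.42 in succinate, with 28 of 60 genes called lower, and -3.94 in pyruvate, with 53 called. These medians are not measured sizes, since 6 of the 60 genes in mutant succinate and 39 in mutant pyruvate were not well above background on 1 array or both. With these genes at their bound the medians were -2.35 and -3.14. The prophage antirepressor (Rpal_3073) changed by -4.17 ± 0.62 in succinate and the tail collar protein (Rpal_3075) by -4.06 ± 0.61. In pyruvate, where 1 of the 2 mutant arrays was not well above background for these genes, they were at least 22.6-fold and 29.6-fold lower and the terminase large subunit (Rpal_3056) at least 17.1-fold. None of these calls held with normexp background. The phage repressor (Rpal_3044) was not well above background in the mutant in either medium and was at least 7.90-fold lower in succinate. A DnaA-domain gene (Rpal_3048) was at least 8.77-fold lower in pyruvate. With normexp background these 2 genes fell less, at -1.37 (limma adjusted p = 0.514) and -1.21 (limma adjusted p = 0.62). The normexp offset of 50 shrinks falls of such dim genes by construction, so these values do not decide how large the falls were. The bounds set the mean of the higher group against the lowest signal well above background on each array of the lower group, or the gene's own where higher. They hold for the main background handling only. Among the 20 genes flanking the run, limma called 0 lower in succinate and 1 in pyruvate, with 4 and 3 lower at an unadjusted p under 0.05. The run's ends were set at its outermost genes called lower in both media, so few calls just outside follow in part from that choice.

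**Figure D2:**
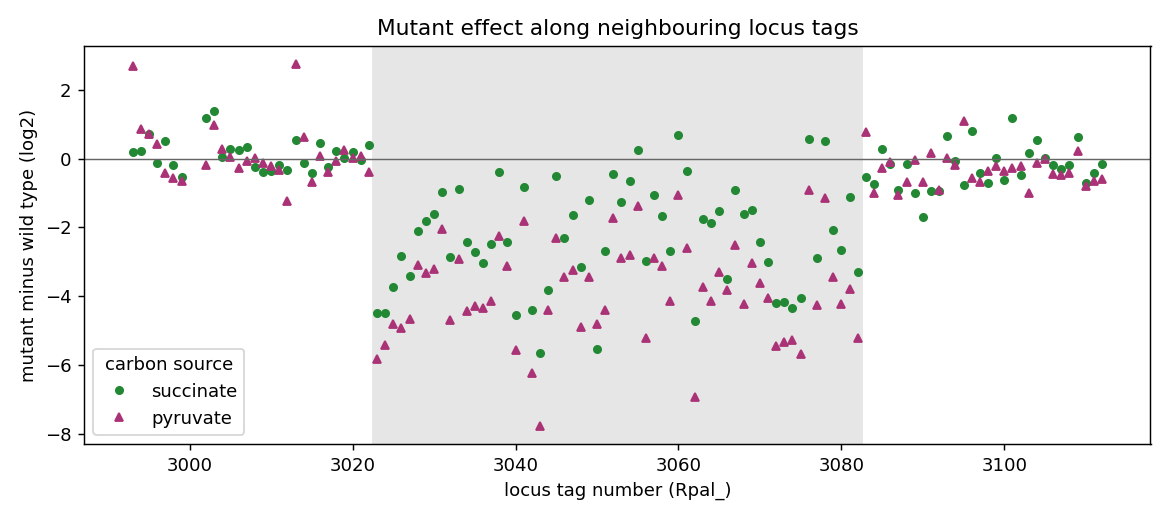
Mutant minus wild type on the log2 scale (y axis) along locus tag numbers (x axis) in succinate (circles) and pyruvate (triangles), with the run of 60 genes shaded. With genes not well above background at their bound the run's median was -2.35 in succinate and -3.14 in pyruvate (-2.42 and -3.94 as fitted and drawn, which are not measured sizes), against -0.16 and -0.09 for the 20 flanking genes. The run ends at its outermost genes called lower in both media, so the flanks are not an independent contrast.

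The mutant effects in succinate and in pyruvate, which share no arrays, had a Pearson r of 0.488 and a Spearman rho of 0.408 across 5227 genes, which are not independent replicates. In both media 33 genes were higher, where 2.92 would overlap by chance if genes were independent, and 79 were lower, where 19.5 would. Of the 79, 28 lay in the run of phage-type genes. A further 4 were higher in succinate and lower in pyruvate, and 9 the reverse. Each strain had its own slide columns in both media, and both effects changed with signal level. Position or array range could therefore raise the correlation and the overlap, which the chance figures do not allow for. The correlation was 0.337 after quantile normalization, 0.338 without wild-type succinate array 2 and 0.387 without the run of phage-type genes.

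The test of the difference itself called 39 genes, 27 with a more positive mutant effect in pyruvate and 12 with a more negative one. With the replicate number as a block the split turned, to 343 and 616 among 959 calls. The labels do not state that these numbers mark a batch. The hydrogenase cytochrome b subunit (Rpal_1156) had the largest difference, 5.16 ± 0.49 (adjusted p = 0.027), lower in the mutant in succinate and higher in pyruvate. Next were Rpal_0816 at 4.67 ± 0.40, Rpal_5164 at 3.98 ± 0.53 and Rpal_1288 at 3.69 ± 0.54, all hypothetical proteins, and the ECF sigma factor (Rpal_5278) at 3.67 ± 0.43. On the other side stood Rpal_1479, a hypothetical protein, at -3.58 ± 0.36, a DUF1127 protein (Rpal_3167) at -3.28 ± 0.49, an OmpA/MotB domain protein (Rpal_1976) at -3.01 ± 0.32, the chemotaxis protein (Rpal_2025) at -2.85 ± 0.43 and an amidohydrolase (Rpal_5178) at -2.83 ± 0.41. The hydrogenase list differed with a camera adjusted p of 4.0e-07 (1 of 10 more positive, 7 when adjusted over the list alone), the Calvin cycle list at 0.00037 (3 of 6, then 4), ribosomal proteins at 0.0069 and NADH:quinone oxidoreductase at 0.0098 with 0 members on either limma count (9 and 5 more positive, 3 and 0 more negative at an unadjusted p under 0.05), and transposases and phage genes at 0.0098 in the negative direction (1 of 65 on both counts). None passed with an estimated correlation (adjusted p = 0.883) or by fry. Normexp background and quantile normalization ended the calls of ribosomal proteins and of transposases and phage genes, which were at 0.079 and 0.15 without wild-type succinate array 1, 0.28 and 0.088 without wild-type pyruvate array 2 and 0.37 each without mutant pyruvate array 1. The phage list was at 0.079 without mutant succinate array 2, and the NADH:quinone oxidoreductase list at 0.16, 0.21 and 0.40 without wild-type succinate array 1, mutant succinate array 2 and mutant pyruvate array 1. The 39 calls became 0 in limma with normexp background (445 genes at an unadjusted p under 0.05 against 923), 380 with quantile normalization, 139 with median scaling, 138 with the deposited values and 218 with a trended robust variance. They became 0 without any one of the 4 wild-type arrays or the 2 mutant succinate arrays (580 to 904 genes at an unadjusted p under 0.05) and 83 without mutant pyruvate array 2.

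**Figure D3:**
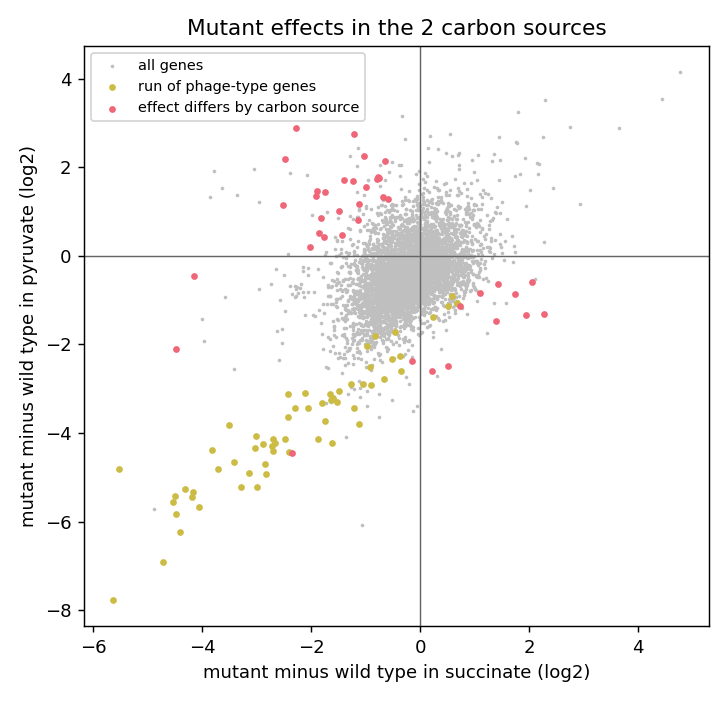
Mutant minus wild type in succinate (x axis) against pyruvate (y axis), log2 scale, 1 point per gene. The run of phage-type genes lies low on both axes, and the 39 genes whose mutant effect differed between carbon sources are marked.

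The third comparison set pyruvate against succinate in the wild type. The 3 genes for ribulose-bisphosphate carboxylase fell on pyruvate, with changes of -5.09 ± 0.26 (Rpal_1748, 34.1-fold), -4.72 ± 0.22 (Rpal_1747) and -2.845 ± 0.281 (Rpal_5122, named after its value was seen). Nitrogenase genes lay higher: 14 of 37 rose and 1 fell, led by the nitrogenase iron protein (Rpal_1623) at 4.50 ± 0.62. The list's shift did not pass with an estimated correlation (adjusted p = 0.896). The uptake hydrogenase small subunit (Rpal_1154) rose by 4.42 ± 0.58, glutamate-ammonia ligase (Rpal_4690), which assimilates ammonium, by 4.85 ± 0.37 and Rpal_0720 by 6.35 ± 0.76. A UspA domain protein (Rpal_1453) fell by 6.44 ± 0.36 (86.9-fold) and the P-type ATPase next to it (Rpal_1452) by 5.28 ± 0.44. In all, 651 genes were higher and 475 lower on pyruvate.

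By list, the Calvin cycle lay lower (camera adjusted p = 0.00018, 4 of 6 lower on both counts), nitrogenase higher (0.0034, 15 higher and 1 lower when adjusted over the list alone), NADH:quinone oxidoreductase lower (0.0034, 5 of 34 lower and 3 higher, then 13 and 3) and aromatic degradation higher (0.046, 6 of 23 higher and 1 lower, then 9 and 2). By fry the adjusted p was 0.0021, 0.26, 0.26 and 0.12. With an estimated correlation the camera adjusted p was 0.806, 0.896, 0.880 and 0.880. Without wild-type succinate array 1 the NADH:quinone oxidoreductase and aromatic degradation lists were each at 0.086, and without wild-type pyruvate array 1 the latter was at 0.055. The P-II protein (Rpal_0277) rose by 2.53 ± 0.28, NADP-dependent isocitrate dehydrogenase (Rpal_4362) by 2.09 ± 0.33, ATP synthase subunit A (Rpal_0914) by 2.41 ± 0.26, cytochrome c oxidase subunit III (Rpal_1639) by 2.60 ± 0.45, copper-containing nitrite reductase (Rpal_4623) by 3.15 ± 0.50 and an FAD-dependent oxidoreductase (Rpal_4092) by 3.23 ± 0.19. Isocitrate lyase (Rpal_4878) fell by 2.53 ± 0.31, a TRAP transporter (Rpal_3949) by 2.48 ± 0.32, and an RND efflux subunit (Rpal_5163) by 3.63 ± 0.26. A sigma54-type regulator (Rpal_1400) was at -4.30 ± 0.57 and a heme receptor (Rpal_2415) at -5.08 ± 1.20, both past the threshold. Ribosomal proteins went both ways, 18 of 52 higher and 22 lower (19 and 22 when adjusted over the list alone), with a median of -0.05 and a mean of 0.03, S12 (Rpal_3672) at 2.35 ± 0.27 and L15 (Rpal_3648) at -1.49 ± 0.28. Among hopanoid genes HpnH (Rpal_4256) rose by 1.61 ± 0.22, HpnC (Rpal_4264) by 1.53 ± 0.28 and the desaturase (Rpal_4262) fell by 1.19 ± 0.23. With normexp background these hopanoid genes were at 1.13, 0.67 and -1.06, and none of them was called. The 1126 calls were 250 with normexp, 1861 with quantile normalization, 746 from the wild-type arrays alone, 227 or 559 without wild-type succinate array 1 or 2, 206 or 442 without wild-type pyruvate array 1 or 2 and 728 without either mutant succinate array. Of the 60 named calls, 22 passed in all 8 leave-outs. The split was 538 higher and 685 lower after median scaling, with a median change over all genes of 0.16 in the main scaling and 0.00 after median scaling.

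The fourth comparison set pyruvate against succinate in the mutant. The hydrogenase cluster rose: the cytochrome b subunit (Rpal_1156) by 6.59 ± 0.35 (96.6-fold), the small subunit HydA (Rpal_1154) by 6.54 ± 0.58, a formation protein (Rpal_1157) by 5.44 ± 0.42, HupE/UreJ (Rpal_1158) by 5.25 ± 0.34, the HypC-type chaperone (Rpal_1159) by 4.82 ± 0.50 and the large subunit (Rpal_1155) by 4.75 ± 0.32. The list had 8 of 10 members higher, 10 when adjusted over the list alone, and a camera adjusted p of 2.6e-07 (adjusted p = 0.968 with an estimated correlation). Of the genes just named, only Rpal_1157 and Rpal_1155 are in that list. The UspA domain protein (Rpal_1453) fell by 6.39 ± 0.36 and the P-type ATPase (Rpal_1452) by 5.11 ± 0.44, close to their changes in the wild type. In all, 534 genes were higher and 489 lower on pyruvate, a split that turned to 591 and 706 with median scaling, 598 and 661 with the deposited values and 86 and 122 with normexp background. In the main scaling 307 were higher and 179 lower in both strains, where 66.5 and 44.4 would overlap by chance, and the changes in the 2 strains, which share no arrays, correlated with r = 0.541 across genes. Each carbon source had its own slide row in both strains, so position could raise these figures too.

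Nitrogenase lay higher in the mutant too (camera adjusted p = 0.0025, and 0.968 with an estimated correlation, 12 of 37 higher and 1 lower, then 14 and 1 when adjusted over the list alone), with the molybdenum-iron protein beta chain (Rpal_5099) at 3.84 ± 0.39. The Calvin cycle lay lower (0.0086, and 0.968 with an estimated correlation, 4 of 6 lower on both counts), with ribulose-bisphosphate carboxylase (Rpal_1748) at -2.60 ± 0.26, and the fall was smaller than in the wild type by 2.49 (interaction adjusted p = 0.044). Pigment synthesis lay lower (0.010, and 0.694 with an estimated correlation, 9 of 24 lower and 1 higher, then 11 and 1), with the magnesium-protoporphyrin IX monomethyl ester anaerobic oxidative cyclase (Rpal_1864) at -1.68 ± 0.26. The pigment list was at 0.092 without mutant pyruvate array 2. By fry the hydrogenase (adjusted p = 0.013), Calvin cycle (0.013) and pigment (0.00057) lists passed in the mutant and nitrogenase (0.31) did not. The P-II protein (Rpal_0277) rose by 3.40 ± 0.28, an antenna subunit (Rpal_3419) by 2.34 ± 0.32, isocitrate dehydrogenase (Rpal_4362) by 2.28 ± 0.33, an NADH dehydrogenase (Rpal_0804) by 2.79 ± 0.22 and HpnC (Rpal_4264) by 1.59 ± 0.28. Of these, isocitrate dehydrogenase (1.60) and HpnC (1.14) were not called with normexp background. The fasciclin protein (Rpal_0221) fell by 4.41 ± 0.54 and a cation efflux protein (Rpal_2718) was at -4.38 ± 0.61, also past the threshold. Further falls were a siderophore receptor (Rpal_2620) at -2.79 ± 0.59 (-1.76 without mutant pyruvate array 2, with its call kept in 6 of 8 leave-outs), cytochrome c552 (Rpal_0849) at -2.59 ± 0.33 and the heat shock sigma factor RpoH (Rpal_0371) at -1.72 ± 0.23. Squalene-hopene cyclase (Rpal_4261) was at least 1.56-fold lower, with 1 of the 2 pyruvate arrays not well above background, and was not called with normexp background (-0.43). The 1023 calls were 208 with normexp, 1564 with quantile normalization, 219 from the mutant arrays alone, 61 or 51 without mutant succinate array 1 or 2 and 658 without mutant pyruvate array 1. Of the 57 named calls, 12 passed in all 8 leave-outs.

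Of the 29 lists, 17 were called by camera in no comparison. By fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, 3 of the 17 were called. Hopanoid synthesis was at a fry adjusted p of 0.0042 for the mutant in succinate and 0.0016 in pyruvate. In each, only 2 of its 7 genes, Rpal_4261 and Rpal_4260, were called, and the list's median change was -0.12 and -0.54. ATP synthase was at 0.033 and 0.0074 for these and 0.028 for the carbon source in the wild type. Fatty acid synthesis was at 0.042 for the mutant in pyruvate and 0.010 and 0.035 for the carbon source in wild type and mutant. The lowest camera adjusted p of the 17 was 0.23 for hopanoid synthesis, 0.47 for isoprenoid precursors, 0.11 for the tricarboxylic acid cycle, 0.14 for pyruvate and glyoxylate enzymes, 0.13 for dicarboxylate transport, 0.13 for ATP synthase, 0.46 for cytochromes, 0.11 for oxidative stress, 0.096 for sigma factors, 0.12 for efflux, 0.12 for fatty acid synthesis, 0.36 for phospholipids, 0.18 for the outer membrane, 0.23 for peptidoglycan, 0.11 for iron uptake, 0.50 for osmotic functions and 0.28 for phosphate.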

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

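The tests of the run of phage-type genes, of the excess of falls and of the hydrogenase list under quantile normalization were chosen after the results were seen. The mutant effect differed between succinate and pyruvate for 39 genes by the test of the difference. Among the genes named, the difference (pyruvate minus succinate, log2) was 5.16 for Rpal_1156, 4.67 for Rpal_0816, 3.98 for Rpal_5164, 3.69 for Rpal_1288, 3.67 for Rpal_5278, 3.30 for Rpal_1398, 3.12 for Rpal_1155, 2.67 for Rpal_0817, 2.49 for Rpal_1748, 2.39 for Rpal_1747 and 1.95 for the CbbX protein Rpal_1749. It was -3.58 for Rpal_1479, -3.28 for Rpal_3167, -3.01 for Rpal_1976, -2.85 for Rpal_2025, -2.83 for Rpal_5178, -2.66 for Rpal_0206 and -2.60 for Rpal_1039. Among lists, the median difference was 1.65 for the Calvin cycle, 1.31 for hydrogenases, 0.20 for ribosomal proteins, 0.21 for NADH:quinone oxidoreductase and -0.64 for transposases and phage genes.

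The hydrogenase list's mutant effect differed between the 2 media by camera with a preset correlation, but not with an estimated correlation (adjusted p = 0.883). Nor did it pass by fry, whose 1 call for the interaction was pigment synthesis (adjusted p = 0.042). A difference in signal range between arrays would shrink its median difference under quantile normalization to under 0.5 of 1.31, and it was 1.26. A single deviating array would do so when left out, and the lowest value over the 8 leave-outs was 0.94, without mutant pyruvate array 1. Both technical explanations are thus argued against for the list's median, and the difference of Rpal_1156, a hydrogenase gene outside the list, ran from 4.74 to 5.58 over the leave-outs, with its call lost in 6 of 8. The genotype remains a candidate explanation as a hypothesis, and slide position, which follows the groups, stays open.

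The run Rpal_3023 to Rpal_3082 was low on the mutant arrays. The run was found by a scan, so the scan was repeated on 10000 orders of the genes shuffled within wild-type level, since a difference in array range predicts like falls at like levels: the lowest median of 15 neighbouring genes was -4.34 in pyruvate and -2.71 in succinate, against no lower than -2.13 and -1.52 in the shuffled orders, and with genes not well above background at their bound it was -3.65 and -2.71 against -1.97 and -1.39, which argues against array range alone. Reduced expression of a region still present and loss of the region cannot be told apart. In mutant pyruvate 18.3% of the run's genes stayed at or above the lowest 1% of other genes. Below that level lay 81.7% in mutant pyruvate and 51.7% in mutant succinate. Of the run's probes, 35.2% and 9.26% were well above background on neither array. Lower in both media were 56 of the 60 genes, while Rpal_3055, Rpal_3060, Rpal_3076 and Rpal_3078 were at 0.24 to 0.68 in succinate, not called. Rpal_3041, Rpal_3060, Rpal_3076 and Rpal_3078 kept the most signal, which could come from cross-hybridisation or from expression. DNA was not measured.

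More genes fell than rose in the mutant in the main scaling; in pyruvate this depended on the scaling, with 383 higher and 308 lower after median scaling, 366 and 303 with the deposited values and 508 and 510 after quantile normalization. Leaving out the run kept 71.0% of calls in succinate and 67.5% in pyruvate on the lower side, so the run alone does not account for it. With genes ranked by mean level over the 8 arrays and split into 5 equal parts, the median change of the dimmest part minus that of the brightest was -0.69 in succinate and -1.11 in pyruvate, but called falls lay in every part: from dimmest to brightest 39, 34, 39, 52 and 60 in succinate and 121, 116, 83, 74 and 60 in pyruvate, against 0, 0, 12, 31 and 36 and 1, 6, 20, 54 and 112 rises. On the same measure array 1 minus array 2 of a group was -0.78 in wild-type succinate, -0.37 in mutant succinate, -0.74 in wild-type pyruvate and -0.86 in mutant pyruvate, so arrays of 1 strain differed in range too. A difference of one sign in all 4 groups is balanced over the strains and does not measure range between them. The 5th percentile over genes was -4.81 and -4.24 on the mutant arrays against -4.17 and -3.23 on the wild-type arrays in succinate. In pyruvate it was -5.53 and -4.16 against -3.84 and -2.97. Range and genotype cannot be told apart, since each strain had its own columns of the slide.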

How the results depend on the processing

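The calls depended strongly on the processing. Normexp background left 27, 13, 250, 208 and 0 calls (mutant in succinate, mutant in pyruvate, carbon source in wild type, carbon source in mutant, interaction) against 303, 647, 1126, 1023 and 39, and 57 named values past the threshold against 200, although 215 of 218 named values kept their sign. Quantile normalization gave 620, 1018, 1861, 1564 and 380, and turned Rpal_4220 (well above background on 1 of 2 mutant arrays) from -2.45 to 0.21 in the pyruvate mutant comparison and the light-harvesting list to higher on pyruvate than on succinate in the mutant (adjusted p = 0.00038; 0.317 to 0.998 under its other settings). Trended robust variance gave 545 and 218 calls for the mutant in succinate and the interaction, and the interaction had 139 with median scaling and 138 with the deposited values. Only the groups compared gave 16, 746 and 219 for the mutant in pyruvate and the carbon contrasts, and 106 named calls. Each array left out gave 7 to 375, 24 to 744, 206 to 1297, 51 to 855 and 0 to 83 calls, and 85 to 181 named calls; a lone array is then assumed to vary like the other groups, and fewer samples lower the power. The correlation of mutant effects was 0.393 with normexp, 0.337 with quantile normalization, 0.368 with probes above background on all 8 arrays, 0.387 without the run (chosen after seeing the data) and 0.338 to 0.574 over the leave-outs. With an estimated correlation 0 of the 26 list calls passed (camera). Pigment synthesis by carbon source in the mutant had an estimated correlation of -0.03, and its camera adjusted p still went from 0.010 to 0.694. Losing a call there thus does not show that correlation between a list's genes undid it. The other called lists had higher estimates, among them 0.85 for light harvesting, 0.84 for nitrogenase, 0.58 for hydrogenases, 0.39 for flagella and chemotaxis and 0.12 for ribosomal proteins. For them the preset of 0.01 may be too low. Fry made 18 list calls, of which 6 were among the 26 and 12 were not. The normexp offset shrinks changes of dim genes by construction. How much of the loss of calls comes from that offset was not tested. Apart from the fewer samples, no other cause of the dependence on processing was tested. Signal over background limits dim genes: between 97.2% and 100% of spots per array were well above it, and the cyclase Rpal_4261 has no value when only probes above background on all 8 arrays are used. Counts under the settings not given here stayed within 1.5 times.

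The replicate numbers were not stated to mark a shared batch. Differences between arrays 1 and 2 correlated by 0.43 to 0.71 across genes over the 6 pairs of groups, and with the replicate number as a block the counts of calls were 1664, 2606, 2134, 2306 and 959; the 1664, 2606 and 959 were 428, 519 and 343 higher and 1236, 2087 and 616 lower, against 27 and 12 for the interaction without the block, and the hydrogenase list in succinate was at 0.0512 (0.00905 to 0.141 over its alternatives at the preset correlation).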

Other observations

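The genes below were chosen after their values were seen. The locus tags Rpal_0815 to Rpal_0817 hold a putative iron oxidase precursor, a hypothetical protein and a cytochrome c family protein. In succinate they changed in the mutant by -1.75 ± 0.28, -2.48 ± 0.29 and -1.82 ± 0.29 on the log2 scale, each past the threshold. In pyruvate Rpal_0815 and Rpal_0816 rose by 1.45 ± 0.28 and 2.19 ± 0.29 and Rpal_0817 was at 0.85 ± 0.29 (adjusted p = 0.095). Near them, a putative NAD-dependent formate dehydrogenase (Rpal_0807) and the accessory protein FdhD (Rpal_0806) rose in the mutant in pyruvate by 1.33 ± 0.34 and 1.28 ± 0.28, while in succinate they were at 0.05 and -0.09; the difference between media was not called for either (adjusted p = 0.23 and 0.15).

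Several genes of unknown function rose in the mutant in both media. They were not among the named genes followed under the alternatives, and normexp background left 8 called rises over all genes in each medium. Rpal_3855 rose by 4.78 ± 0.44 in succinate and 4.15 ± 0.44 in pyruvate, Rpal_4681 by 4.45 ± 0.40 and 3.54 ± 0.40, Rpal_3610 by 3.65 ± 0.31 and 2.89 ± 0.31, and the DUF1501 and DUF1800 genes Rpal_4116 and Rpal_4117 by 2.27 ± 0.24 and 2.17 ± 0.44 in succinate and by 2.70 ± 0.24 and 1.84 ± 0.44 in pyruvate. The heme receptor (Rpal_2415) had an SD of 3.08 between the 2 mutant pyruvate arrays against 0.11 in wild-type pyruvate.

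A hypothesis was that mutant effects follow the order of genes. The mean mutant effect of neighbouring locus tags correlated with r = 0.392 over 5098 pairs, the run of phage-type genes left out, against at most 0.058 in 10000 random orders (p = 1e-04, the smallest they can give). These orders were shuffled without regard to signal level, unlike those for the run. The mutant effect changed with level (dimmest part minus brightest part -0.69 in succinate and -1.11 in pyruvate). Neighbours that change together, as in shared transcripts, and neighbours that merely have like levels can therefore not be told apart. Shared transcripts were not measured.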
